A study of Mus musculus with 3 samples.

How the data were processed

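RNA was measured in bone marrow-derived macrophages of C57BL/6 mice, which are marrow cells grown for 6 days with macrophage colony-stimulating factor (M-CSF, 20 ng/ml) in medium with 10% fetal bovine serum. Per the labels' protocols, RNA was taken up in Trizol and 1 µg of total RNA per sample went into an Illumina TruSeq library. There were 3 libraries, 1 from wild-type cells, 1 from cells lacking the long non-coding RNA gene Gm1082 and 1 from cells lacking lnc57Rik. The labels name no stimulus.

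The authors deposited 1 table of mRNA transcripts and 1 of long non-coding RNA (lncRNA) transcripts. The mRNA table lists 62690 Ensembl transcripts of 15546 gene symbols. The lncRNA table lists 49636 transcripts, of which 399 have Ensembl identifiers, 45739 have NONCODE identifiers and 3498 have identifiers starting with MERGE, called assembled transcripts here. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm9. The quantifier, its handling of strand and the transcript annotation are not given in the sources used here. The positions in the tables fit GRCm38 instead. Of the 14924 mRNA symbols that are also in a RefSeq gene table of GRCm38, 14909 (99.9%) overlapped the gene of that name, and positions are given on GRCm38.

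Each deposited table holds 1 abundance per transcript and library, and the header does not name its unit. The deposited values were taken as FPKM (fragments per kilobase of transcript, scaled to library depth). In transcripts of the lncRNA table with a low product of value and genomic span, that product mostly fell on whole multiples of 1 step per library. Within 0.02 of a whole number lay 85.9% of 6783 such transcripts in wild type, 86.2% of 5926 in the Gm1082 knockout and 87.0% of 6788 in the lnc57Rik knockout, against 4% by chance. If 1 step is 1 read, a value of 1 in a transcript of 1 kb stands for 79.9 reads in wild type, 74.3 in the Gm1082 knockout and 75.9 in the lnc57Rik knockout. A TPM table over more transcripts would look alike and would differ by 1 factor per library. No read counts per gene were used here, so no interval for counting error is given.

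The authors also deposited a log2 ratio, a p-value and an adjusted p-value for each knockout against wild type, per the file headers. In the mRNA table the deposited log2 ratio lay within 0.02 of the log2 ratio of the abundances plus a constant for most transcripts, 98.7% with a constant of -0.07 for the Gm1082 knockout and 98.6% with -0.12 for the lnc57Rik knockout. The method behind the deposited p-values is not given in the sources used here. Their standard errors, recovered from each log2 ratio and its p-value, were almost the same for all abundant mRNA transcripts, with a median of 0.655 in either comparison. They rest on a nearly common spread, not on replicates of a genotype, and whether it was assumed or estimated is not given. The deposited p-values are cited only as counts from the authors' deposited table.

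Transcript abundances were summed per gene symbol in the mRNA table. lncRNA transcripts without a symbol were kept single. Genes with a mean of 1 FPKM or more over the 3 libraries were compared, which left 10484 mRNA genes and 10195 lncRNA genes. Ratios are log2((a + 1)/(b + 1)), with a pseudocount of 1, and this scale understates the differences of genes with low values. A gene was called higher or lower at a log2 ratio of at least 1 in size, which is 2-fold. This is a rule of size, and the words rose and fell refer to it. With 1 library per genotype there is no replicate check, no test was run and no p-value is given for any of these ratios. A difference between libraries may belong to the culture, the animal or the library as much as to the genotype.

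For 40 gene lists (pathways, cell types and signs of library quality), the median log2 ratio of the measured members is given with its percentile among 10000 random lists of the same size, matched on mean expression in 10 bins. Medians below percentile 2.5 or above 97.5 are said to stand apart. The percentile describes these libraries, and genes of a list that vary together make extremes more frequent than for random genes. The comparison of both knockouts with the same wild-type library was set against 100 simulated sets of 3 libraries with no genotype effect. Their deviations were drawn, with random sign, from the differences between the knockouts in genes at like expression. KEGG pathways named in the authors' deposited mRNA table, with 15 to 150 measured genes, were treated like the lists with 2000 random sets each.

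The samples, the comparisons, the size rule, the gene lists and the rule for named genes were fixed before the data were examined. That rule takes, per knockout, the 8 genes with the largest positive and the 8 with the largest negative log2 ratio among genes with a mean of 5 or more. It adds the 3 members with the largest ratio in size of each list that stands apart or has at least 3 called members, the 4 highest and 4 lowest lncRNA, and Gbp2, Casp4, Gsdmd, Casp1, Nlrp3, Il1b, Il18 and Wdr5 in any case. For the knockouts against each other it takes the 5 largest in each direction. Any other gene in the text was chosen after its values were seen.

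In data simulated from the wild-type values for a comparison of the Gm1082 knockout with wild type, over 10484 genes, the size rule found 50 of 50 genes raised 4-fold, 50 of 50 lowered 4-fold and 50 of 50 raised 2.8-fold. It found 0 of 50 raised 1.4-fold and called 0 of 10284 unchanged genes. The changed genes were picked among those at 5 FPKM or more in wild type, so recovery of lower genes was not checked. That simulation held only the counting error of reads, not the spread between cultures or libraries, so it says nothing about false calls from that spread. In a separate simulation, with random spread between libraries and no counting error, the 1 raised list came out above percentile 97.5. In the lnc57Rik library of that separate simulation, 6 of 100 random lists lay outside the percentile bounds.

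The alternatives were pseudocounts of 0.1 and 5, no minimum on the mean, a minimum of 5, 3 rescalings (median-of-ratios factors, equal totals, and totals without the 100 most abundant genes), the most abundant transcript in place of the sum, and size rules of 1.5-fold and 4-fold. In 2 further alternatives, the abundances of lncRNA-table transcripts overlapping a gene on the same strand were added to that gene, or assembled transcripts were left out. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.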

Results

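The 3 libraries held 277408 FPKM in the mRNA table for wild type, 269163 for the Gm1082 knockout and 268967 for the lnc57Rik knockout. The lncRNA table added 118838, 117313 and 118771. Genes with 1 FPKM or more numbered 10241, 10272 and 10647 of the mRNA symbols. The 100 most abundant genes held 33.1% of the mRNA abundance in wild type, 30.9% in the Gm1082 knockout and 27.6% in the lnc57Rik knockout. Across genes, which are not independent replicates, log2 values of the Gm1082 knockout and wild type had a Pearson r of 0.961, against 0.932 for the lnc57Rik knockout and wild type. Macrophage genes varied in level, from Csf1r, the receptor for M-CSF, at 134, 111 and 88.9 FPKM in wild type, the Gm1082 knockout and the lnc57Rik knockout, to the receptor kinase gene Mertk at 2.53, 2.53 and 2.32 FPKM. Of 5 sex-chromosome genes 4 were measured, all of them Y-linked (Ddx3y, Kdm5d, Uty and Eif2s3y), and 0 of them passed the size rule in either knockout.

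The targeted genes would come first, as a check of the genotype labels. 0 transcripts carry the symbol Gm1082 or lnc57Rik in the tables used here. The GRCm38 gene table gives Gm1082 as another name of Arhgap33os, and 0 transcripts overlap that gene. The expression of both targets was therefore not analysed here, and the genotypes rest on the labels alone.

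The comparison of the Gm1082 knockout with wild type asks which transcripts differ in macrophage cultures without this lncRNA. These libraries also held much RNA of neutrophil genes (see Other observations), and the share of each cell type was not measured. Hilpda, a lipid droplet protein induced by low oxygen (chromosome 6, 29272488 to 29275446), rose from 1.15 to 166 FPKM, and Egln3, an oxygen-sensing prolyl hydroxylase, rose from 8.62 to 236 FPKM. Acod1, the enzyme that makes itaconate, fell from 148 to 8.79 FPKM, and haptoglobin (Hp), which binds free haemoglobin, fell from 874 to 41.6 FPKM. The 25 neutrophil markers had a median log2 ratio of -0.45, with 3 past the size rule. In all, 164 mRNA genes rose and 141 fell, and the median of all genes was 0.01.

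Among the 8 largest increases, Rhog, a small GTPase, rose from 2.45 to 140 FPKM, and Ifitm2, an interferon-induced membrane protein, rose from 5.41 to 228 FPKM. The other 4 were histone genes, namely Hist1h3c, Hist2h3c2, Hist1h1e and Hist1h2br, with log2 ratios of 6.17, 5.28, 4.58 and 4.30. With the most abundant transcript Hist1h2br stood at 0.10. Histone genes are near-identical copies whose reads can be shared out differently between libraries, so their single values are uncertain, and Hist1h2ae went the other way, from 25.8 to 0.248 FPKM. Besides Hp, the largest decreases were in Bri3 (log2 ratio -4.60), Cd274, the gene of the checkpoint ligand PD-L1 (-4.35), Cmtm6, which stabilises PD-L1 at the cell surface (-4.18), AC140267.1 (-4.13) and Uqcrb, a subunit of respiratory complex III (-4.11). Kbtbd7 was listed at 16.3 FPKM in wild type, at 0 in the Gm1082 knockout and at 11.9 in the lnc57Rik knockout.

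Transcripts of the lncRNA table that overlap a gene on the same strand can hold reads of that gene. Of the 305 called genes 189 had such a transcript with a value above 0, and with its abundance added 109 of them lost the call and 80 kept it. Cd274 then had a log2 ratio of -0.60 and Kbtbd7 one of -0.84, below the size rule. The transcript added at Cd274 changed little, from 23.7 to 29.9 FPKM, while Cd274 itself went from 22.6 to 0.160 FPKM. Adding a nearly constant value makes any ratio smaller in size, so the lost call at Cd274 does not show that reads moved. Hp kept a ratio of -2.48, Bri3 of -3.30, Egln3 of 1.63, Ifitm2 of 3.04 and Rhog of 4.05, while Hilpda stayed at 6.27 and Acod1 at -3.92.

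Of 33 measured inflammatory mediators 4 rose, 2 fell and 27 did neither, with a median of 0.26 at percentile 100. Osm, the cytokine oncostatin M, rose from 0.821 to 11.8 FPKM and Ptgs2, the inducible cyclooxygenase, from 75.8 to 254 FPKM. Of 16 chemokine genes 2 rose and 0 fell, with a median of 0.32. Cxcl16 went from 4.17 to 19.1 FPKM and Ccl24 from 1.08 to 3.18 FPKM, and with overlapping transcripts added their ratios were 0.32 and 0.53, below the size rule. Of 38 pattern recognition genes 1 rose, 1 fell and 36 did neither, with a median of 0.16. Irf5, a transcription factor of inflammatory cytokine genes, fell from 35.3 to 3.99 FPKM, and Tlr9 rose from 2.70 to 6.69 FPKM.

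Of 48 interferon-stimulated genes 3 rose, 0 fell and 45 did neither, with a median of 0.16. Ifi205 rose by a log2 ratio of 1.85, to 7.31 FPKM. The calls of Ifi203 (1.09) and Dhx58 (1.09) did not hold with overlapping transcripts added, at -0.10 and 0.16. Of 18 guanylate-binding proteins and immunity-related GTPases, interferon-induced proteins of cell-autonomous defence, 1 rose and 17 did neither, with a median of 0.34. Tgtp1 was the riser, from 0.0671 to 1.46 FPKM, and its ratio was 0.02 with overlapping transcripts added. Of 23 genes of MHC class I presentation 2 rose and 0 fell, H2-K1 from 141 to 358 FPKM and H2-Q6 from 25.5 to 78.6 FPKM, and H2-K1 stood at 0.25 with overlapping transcripts added and H2-Q6 at 0.77 with the most abundant transcript, both below the size rule. The 17 genes of MHC class II presentation had a median of -0.21, with 0 up and 1 down, H2-DMb1, from 7.51 to 2.16 FPKM.

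Of 25 neutrophil markers 3 fell, 0 rose and 22 did neither, at percentile 0. Retnlg fell from 50.6 to 16.9 FPKM, BC100530 from 16.6 to 6.43 FPKM and Ly6g from 33.9 to 14.9 FPKM. The ratio of BC100530 was -0.31 with the most abundant transcript, and that of Ly6g was -0.96 with a pseudocount of 5, below the size rule. The primary granule genes Elane, Mpo, Prtn3 and Ctsg had ratios of 0.14, 0.23, 0.49 and 0.68. Of 17 monocyte markers 3 fell and 0 rose, with a median of -0.24. Besides Hp, these were Fn1, the gene of fibronectin, from 325 to 110 FPKM, and S100a4, from 25.4 to 11.3 FPKM. Of 33 macrophage identity genes 2 rose and 1 fell, without the list standing apart. Itgam, the integrin chain CD11b, rose from 33.1 to 159 FPKM, Laptm5 rose from 78.0 to 168 FPKM and Lyz2, lysozyme, fell from 1228 to 524 FPKM. The 71 cytosolic ribosomal proteins had a median of -0.23, with 0 up and 1 down, Rps27a, from 195 to 76.6 FPKM.

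Of 27 glycolysis and hypoxia genes 2 rose and 0 fell, Egln3 and the lactate exporter Slc16a3, which went from 85.3 to 204 FPKM, and the list's median was 0.13. Of 22 genes of lipid efflux and storage 1 rose, Hilpda, and 2 fell, Cpt1a and Scd1. The ratio of Scd1 was -1.05, but -0.07 with overlapping transcripts added and -0.33 with a pseudocount of 5, below the size rule. Cpt1a, the entry enzyme of mitochondrial fat oxidation, was listed at 6.89, 0 and 10.2 FPKM in wild type, the Gm1082 knockout and the lnc57Rik knockout. Of 33 immediate early and heat shock genes 0 rose and 3 fell. These were Fosb, from 3.71 to 0.597 FPKM, and the paralogs Hspa1a (-1.05) and Hspa1b (-3.59), whose ratios became 1.53 and 2.41 with overlapping transcripts added. The 21 inflammasome and pyroptosis genes had 0 up and 0 down. Il1b stood at 1871 FPKM in wild type and 1894 in the Gm1082 knockout, Casp1 at 21.8 and 28.2, Casp4 at 49.7 and 52.6, Gsdmd at 12.7 and 10.4, Nlrp3 at 3.86 and 2.94, Il18 at 2.29 and 1.03 and Gbp2 at 14.6 and 18.7. Wdr5, a subunit of H3K4 methyltransferase complexes, stood at 16.7 and 16.3 FPKM. B cell markers had 0 up and 0 down of 12, with a median of 0.28, and the replication-dependent histones had 2 up and 2 down of 26, with a median of 0.42.

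Smaller shifts remained. Of 24 cholesterol synthesis genes 1 fell, Tm7sf2, from 11.6 to 4.90 FPKM, with a median of -0.16. Of 32 genes of the unfolded protein and integrated stress response 1 rose, Ddit4, a stress-induced inhibitor of mTORC1, from 6.27 to 105 FPKM, with a median of 0.17, and its ratio was 0.83 with overlapping transcripts added. The 27 autophagy genes had a median of 0.20 with 0 past the size rule. Of 14 dendritic cell markers 1 rose, Ccr7, from 23.4 to 51.8 FPKM. With the most abundant transcript in place of the sum, the lists for B cell markers, dendritic cell markers, autophagy, glycolysis, pattern recognition and MHC class II no longer stood apart. A pseudocount of 5 ended the calls of Ifi205, Tlr9, H2-DMb1, Tm7sf2 and Fosb, which have low values. It also ended that of S100a4, whose ratio of -1.10 lay close to the size rule.

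The comparison of the lnc57Rik knockout with wild type asks the same of the other lncRNA. Guanylate-binding proteins and immunity-related GTPases rose together, 15 of 18, and Gbp2 (chromosome 3, 142620602 to 142638008) went from 14.6 to 64.1 FPKM. Of 26 replication-dependent histones 20 rose, and smaller parts of other groups did, 9 of 23 genes of MHC class I presentation, 7 of 17 of class II presentation and 8 of 46 cell cycle genes. Of 12 measured B cell markers, out of 16 listed, 10 rose, and Cd79b, a chain of the B cell receptor, went from 1.86 to 49.1 FPKM. The rise itself can bring a marker past the minimum mean. Fcrla stood at 0.254 FPKM in wild type, 1.23 in the Gm1082 knockout and 6.44 in the lnc57Rik knockout. Nlrp3, the inflammasome sensor, rose from 3.86 to 43.5 FPKM, while Ptges, a prostaglandin E synthase, fell from 23.2 to 0.427 FPKM. In all, 506 mRNA genes rose and 200 fell, and with median-of-ratios factors, which moved the median of all genes by -0.12 from 0.09, 420 rose and 253 fell.

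**Figure D1:**
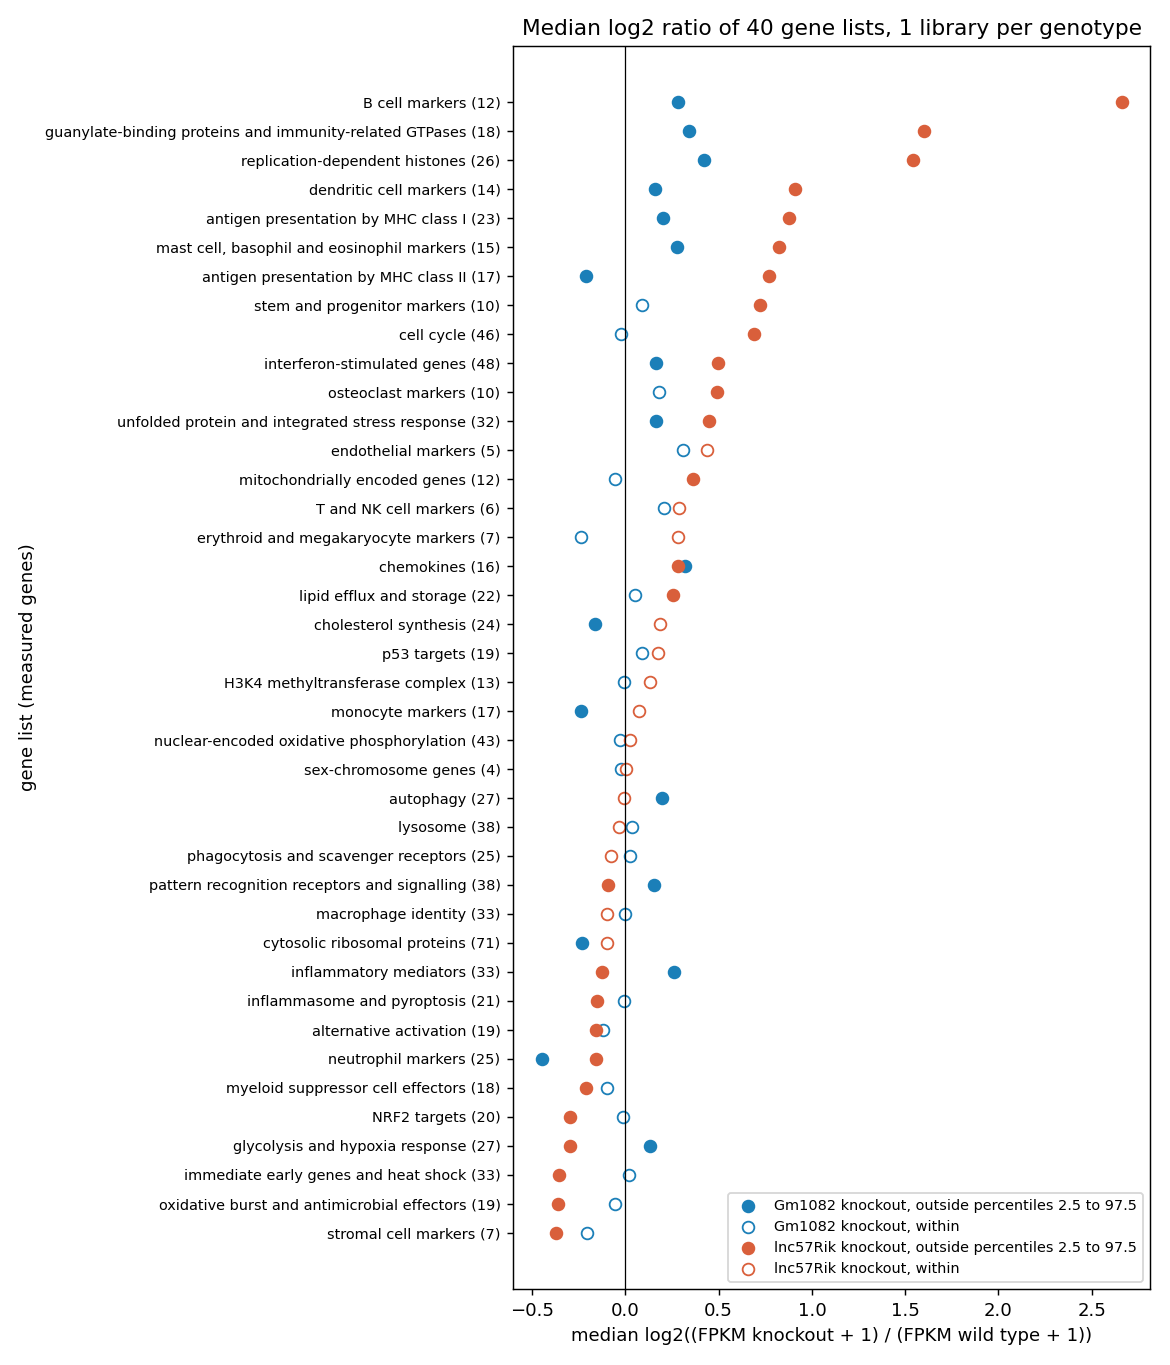
Median log2 ratio of the 40 gene lists in each knockout against wild type, 1 library per genotype, with the measured genes of each list in brackets. Filled points stand apart from matched random lists. B cell markers lie furthest to the right in the lnc57Rik knockout, at 2.66, and neutrophil markers furthest to the left in the Gm1082 knockout, at -0.45.

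The guanylate-binding protein and GTPase list had a median log2 ratio of 1.60 at percentile 100, with 0 of 18 lower and 3 that did neither. Gbp4 rose from 1.23 to 16.6 FPKM, Tgtp2 from 1.87 to 19.1 FPKM and Tgtp1 from 0.0671 to 7.69 FPKM. Against these rises, Gbp9 went from 3.28 to 4.41 FPKM. Of 48 interferon-stimulated genes 10 rose, 1 fell and 37 did neither, with a median of 0.50. Ifi205 rose by a log2 ratio of 2.19 and Ifi203 by 2.29, while Ifit2 fell from 8.01 to 0.339 FPKM. In the same library the B cell markers had a median log2 ratio of 2.66.

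**Figure D2:**
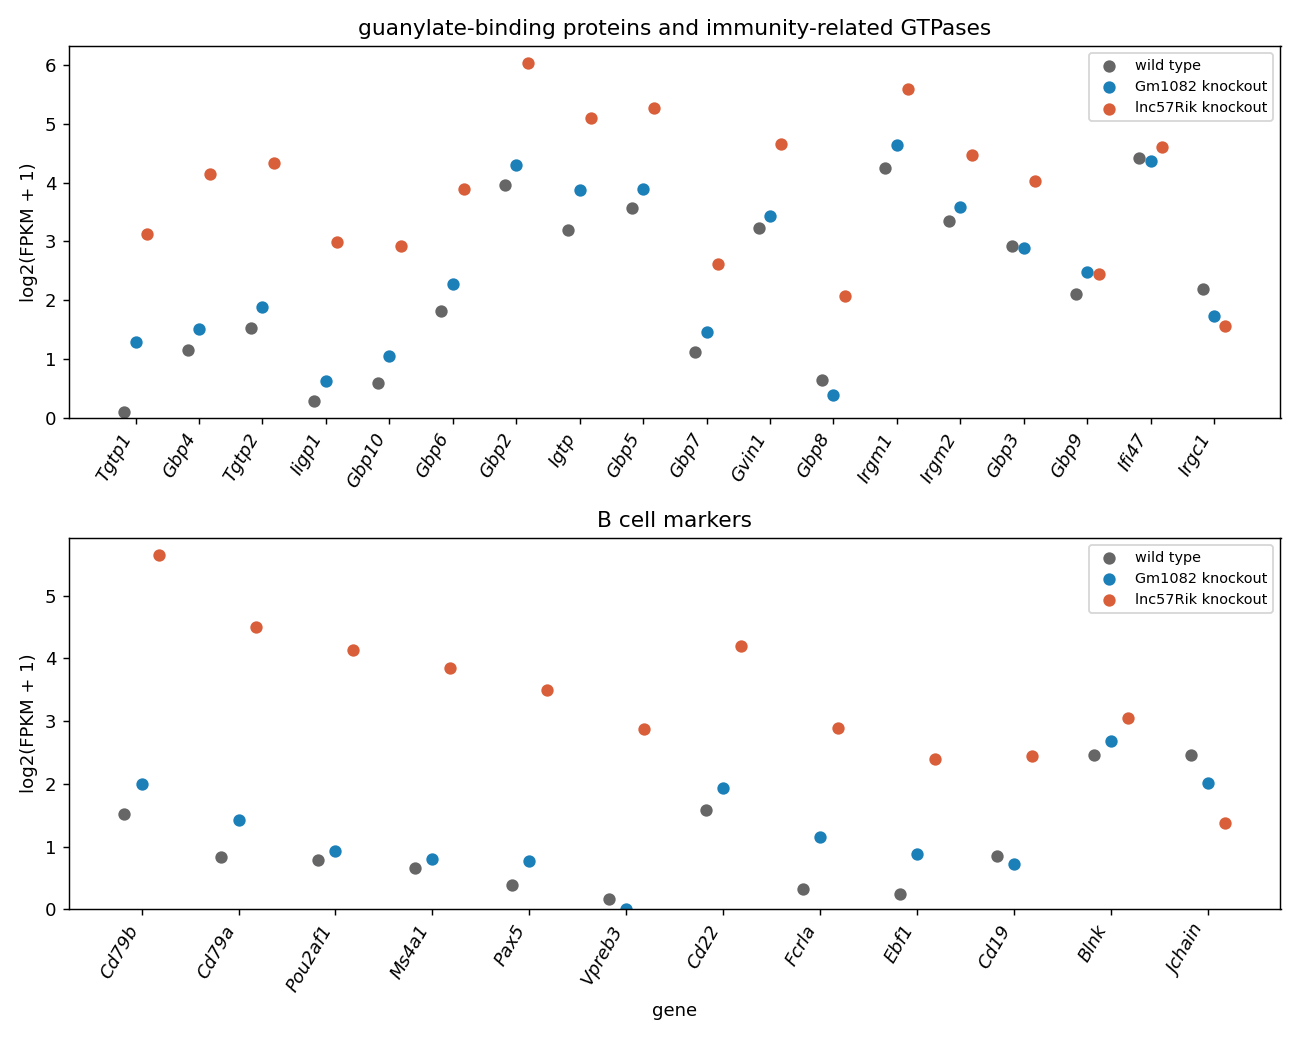
Abundance of each measured gene in the 3 libraries, as log2(FPKM + 1), for guanylate-binding proteins and immunity-related GTPases and for B cell markers. Each point is 1 library. The lnc57Rik knockout is highest for most genes, with exceptions such as Irgc1 and Jchain, where it is lowest.

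Of 17 genes of MHC class II presentation 7 rose, 1 fell and 9 did neither, with a median of 0.77 at percentile 100. Ciita, the master regulator of class II genes, rose by a log2 ratio of 2.30 and Cd83 from 2.51 to 16.8 FPKM, while H2-DMb1 fell from 7.51 to 0.329 FPKM. The abundant class II genes H2-Ab1 and Cd74 did not pass, at 152 and 156 FPKM and at 434 and 585 FPKM. Of 23 genes of MHC class I presentation 9 rose, 2 fell and 12 did neither, with a median of 0.88. The immunoproteasome genes Psmb9 and Psmb10 rose from 3.12 to 12.2 FPKM and from 15.1 to 47.8 FPKM, and H2-Q4 rose from 26.5 to 95.3 FPKM. The 2 that fell were B2m, from 959 to 466 FPKM, and H2-Q7, from 10.1 to 4.34 FPKM. B cells express class II genes and several class I genes, and B cell markers were higher in this library.

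Of the B cell markers, besides Cd79b, Cd79a rose from 0.791 to 21.6 FPKM, the coactivator Pou2af1 from 0.722 to 16.6 FPKM and Ms4a1, the gene of CD20, from 0.584 to 13.5 FPKM. Jchain, a plasma cell gene, fell from 4.50 to 1.60 FPKM. Of 14 dendritic cell markers 5 rose and 0 fell, with a median of 0.91. Ly6d, which lymphoid cells also express, rose from 1.72 to 40.6 FPKM, Fscn1 from 13.4 to 60.2 FPKM and Dpp4 from 0.523 to 5.12 FPKM. Of 15 mast cell, basophil and eosinophil markers 6 rose and 0 fell, with a median of 0.82, among them Ear1, from 13.1 to 35.8 FPKM. Of 10 stem and progenitor markers 2 rose, with a median of 0.72, and of 10 osteoclast markers 1 rose, Itgb3, from 1.72 to 5.18 FPKM. With the most abundant transcript the medians of these lists were 0.42 and 0.33, and neither stood apart. Of 25 neutrophil markers 5 fell and 0 rose, with a median of -0.16, at percentile 2.38, or 10.1 with the most abundant transcript per gene. Retnlg fell from 50.6 to 13.8 FPKM and Cxcr2, a neutrophil chemokine receptor, from 34.9 to 11.8 FPKM, and the ratio of Cxcr2 was -0.87 with the most abundant transcript, below the size rule. Of 6 measured T and NK cell markers 2 rose, with a median of 0.29 that did not stand apart. With no minimum on the mean their median was 0.24 over 19 genes, at percentile 99, and stood apart.

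Of 46 cell cycle genes 8 rose, 0 fell and 38 did neither, with a median of 0.69 at percentile 100. Cdc45, a subunit of the replicative helicase, rose from 0.0150 to 9.54 FPKM, the helicase subunit Mcm6 by a log2 ratio of 1.22 and thymidine kinase Tk1 from 5.44 to 13.8 FPKM. Of 26 replication-dependent histones 20 rose, 0 fell and 6 did neither, with a median of 1.54. Their mRNA lacks a poly(A) tail, so their level also follows how a library is made, and as near-identical copies they are uncertain one by one. Of the 8 largest increases in this comparison 6 were histone genes, led by Hist2h2aa1, from 0.150 to 208 FPKM. The other 2 were Ifitm2, from 5.41 to 165 FPKM, and Rhog, from 2.45 to 78.4 FPKM. The 12 measured mitochondrially encoded genes had a median of 0.36, with 0 past the size rule. B cell markers were higher in this library together with these groups.

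Among 21 inflammasome and pyroptosis genes 2 rose and 2 fell, and the median was -0.15 where the mean was 0.07. With the most abundant transcript the median was -0.02 at percentile 24.1, so the list no longer stood apart. The rise of Nlrp3 (chromosome 11, 59541568 to 59566956) lay in 1 transcript, ENSMUST00000079476, listed at 0 in wild type, 0 in the Gm1082 knockout and 41.3 FPKM in the lnc57Rik knockout, while ENSMUST00000101148 stood at 3.67, 2.72 and 1.97 FPKM. Zbp1, a sensor of nucleic acids, rose from 18.0 to 48.4 FPKM, and Txnip fell from 86.8 to 22.6 FPKM. Il1b stood at 1871 and 1508 FPKM, Casp1 at 21.8 and 28.0, Casp4 at 49.7 and 39.6, Gsdmd at 12.7 and 20.8, Il18 at 2.29 and 1.51 and Wdr5 at 16.7 and 18.0, none past the size rule.

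Inflammatory mediators moved both ways, with 6 of 33 up, 3 down, a median of -0.13 at percentile 2.25, or 7.9 with the most abundant transcript, and a mean of 0.01. Osm rose from 0.821 to 15.4 FPKM, and the acute-phase gene Saa3 fell from 1452 to 382 FPKM. Of 16 chemokines 5 rose and 0 fell, with a median of 0.28, or 0.09 with the most abundant transcript and 0.12 with overlapping transcripts added, where the list no longer stood apart. Ccl22 rose from 64.5 to 246 FPKM and Ccl5 from 108 to 273 FPKM. Among genes of alternative activation 5 of 19 rose, Retnla from 0.503 to 5.42 FPKM among them, and 1 fell, the arginase gene Arg1, from 797 to 321 FPKM, with a median of -0.16 and a mean of 0.25. With no minimum on the mean that median was -0.03 at percentile 13.4. Of 18 myeloid suppressor cell effectors 0 rose and 4 fell, with a median of -0.21 at percentile 2.27, or 11.3 with overlapping transcripts added. Of 33 macrophage identity genes 3 rose and 1 fell, Irf8 rising from 26.5 to 72.2 FPKM, Itgam from 33.1 to 185 FPKM and Lyz2 falling from 1228 to 568 FPKM. The list's median was -0.10 and did not stand apart, but it did with a mean of 5 or more (-0.19) and in 3 other alternatives. Of 38 pattern recognition genes 4 rose, among them Tlr9, from 2.70 to 12.5 FPKM, and 1 fell, Ripk2, with a median of -0.10 and a mean of 0.05. The calls of Traf3 and Clec7a did not hold. Traf3 (1.32) stood at 0.87 with overlapping transcripts added and at -0.31 with the most abundant transcript. Clec7a (1.06) stood at 0.93 with median-of-ratios factors. The ratio of Ripk2 was -1.18, or 0.45 with overlapping transcripts added and -0.23 with the most abundant transcript, so this call did not hold, and the list stood at percentile 5.75 with overlapping transcripts added. Of 32 genes of the unfolded protein and integrated stress response 3 rose, among them the serine pathway genes Shmt2 (log2 ratio 1.26) and Psat1 (1.14), and 1 fell, with a median of 0.45.

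Genes of oxidative burst and antimicrobial defence had 1 up, 5 down and 13 of 19 neither, with a median of -0.36. Acod1 rose from 148 to 511 FPKM. Cyba, the p22phox chain of the NADPH oxidase (chromosome 8, 122424776 to 122432930), went from 161 to 13.6 FPKM. In its place the assembled transcript MERGE.35122.1, on the same strand and spanning 122391681 to 122432930, was listed at 0, 0 and 231 FPKM, and with overlapping transcripts added the ratio of Cyba went from -3.47 to 0.56. Of 33 immediate early and heat shock genes 1 rose and 4 fell, with a median of -0.36, and Hspb1 fell from 7.73 to 0.428 FPKM. Of 20 NRF2 targets, genes of the oxidative stress response, 1 rose and 2 fell, with a median of -0.30, and glutathione reductase, Gsr, fell from 223 to 35.0 FPKM. With overlapping transcripts added Gsr kept its call at -1.74, while the riser, Slc48a1, went from 1.87 to 0.17 and Slc7a11 from -1.06 to -0.07. Of 27 glycolysis and hypoxia genes Egln3 rose and Pfkfb3, a regulator of glycolysis, fell from 159 to 52.1 FPKM, with a median of -0.30, and Egln3 stood at 0.80 with overlapping transcripts added. C5ar1, the receptor for complement C5a, fell from 44.1 to 4.78 FPKM.

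**Figure D3:**
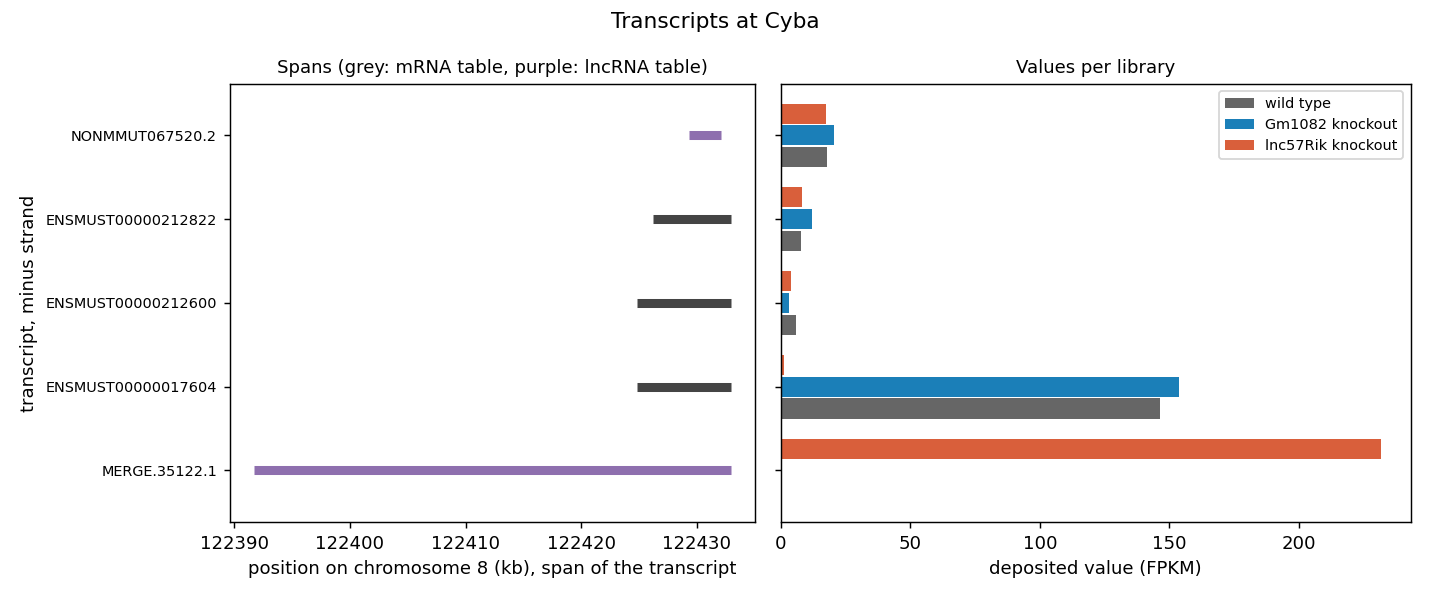
Transcripts of at least 1 FPKM in some library that overlap Cyba on its strand, with their spans on chromosome 8 in kb (grey for the mRNA table, purple for the lncRNA table) and their FPKM in the 3 libraries. ENSMUST00000017604 stood at 146, 154 and 1.31 FPKM in wild type, the Gm1082 knockout and the lnc57Rik knockout, and MERGE.35122.1 was listed at 0, 0 and 231 FPKM.

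The largest decreases were in Bcl2a1d, a survival factor of the BCL2 family (log2 ratio -5.54), Rab20 (-4.77), Ptges (-4.08), Cyba (-3.47), Steap4, a metalloreductase (-3.18), the lipid droplet coat protein Plin3 (-3.09) and Ms4a4a (-3.07). AC161165.4 was listed at 11 FPKM in wild type, 15 in the Gm1082 knockout and 0 in the lnc57Rik knockout. With overlapping transcripts added, Bcl2a1d stood at -2.27, Rab20 at -1.75, Ptges at -1.47, Ms4a4a at -1.67 and Plin3 at -0.83, and of the 362 called genes with such a transcript 126 lost the call and 236 kept it, out of 706 called genes in all. A pseudocount of 5 ended the calls of Mcm6, Tk1, Shmt2, Psat1, Retnla, Dpp4 and Itgb3.

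Set directly against the Gm1082 knockout, the lnc57Rik knockout had 428 genes higher and 175 lower (71.0% higher), or 325 higher and 224 lower (59.2%) with median-of-ratios factors, which moved the median of all genes by -0.10. Of 18 guanylate-binding proteins and GTPases 13 were higher, with a median of 1.31, and of 12 B cell markers 10 were higher. Of 46 cell cycle genes 10 were higher and 36 passed neither way, with a median of 0.74. This comparison shares the lnc57Rik library with the one against wild type. MHC class II genes had a median of 0.92. Inflammatory mediators had 2 of 33 up, 5 down and a median of -0.40. The largest increases were in Hist2h2aa1, Hist2h3c1, Hist1h2ae, Acod1 (5.71) and Cd274 (4.82, or 1.00 with overlapping transcripts added), and the largest decreases in Rab20 (-5.25), Ptges (-5.21), Hilpda (-4.77), AC161165.4 and Bcl2a1d (-3.72). With overlapping transcripts added, Rab20 stood at -2.16, Ptges at -2.13 and Bcl2a1d at -0.86, below Hilpda in size, which stayed at -4.77.

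Of the genes called in either knockout, 100 were higher in both, among them Osm, Itgam, Rhog and Ifitm2, and 47 were lower in both, among them Lyz2, Fn1, Retnlg, Ly6g and Rps27a. With overlapping transcripts added, 70 were higher and 48 lower in both. Both comparisons share the wild-type library, and simulated libraries with no genotype effect gave a median of 113 (88 to 134) higher in both and 107.5 (87 to 142) lower in both. The spread simulated was that between the knockouts, any true difference between them included, so these numbers may be too high as a reference. Independent lists would share 7.92 and 2.69. The correlation across genes was 0.453, against 0.502 in the simulation, and the covariance 0.119 against 0.159. As there is 1 wild-type library it could not be split, and part or all of the overlap may come from it. Opposite directions were seen in 4 genes.

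**Figure D4:**
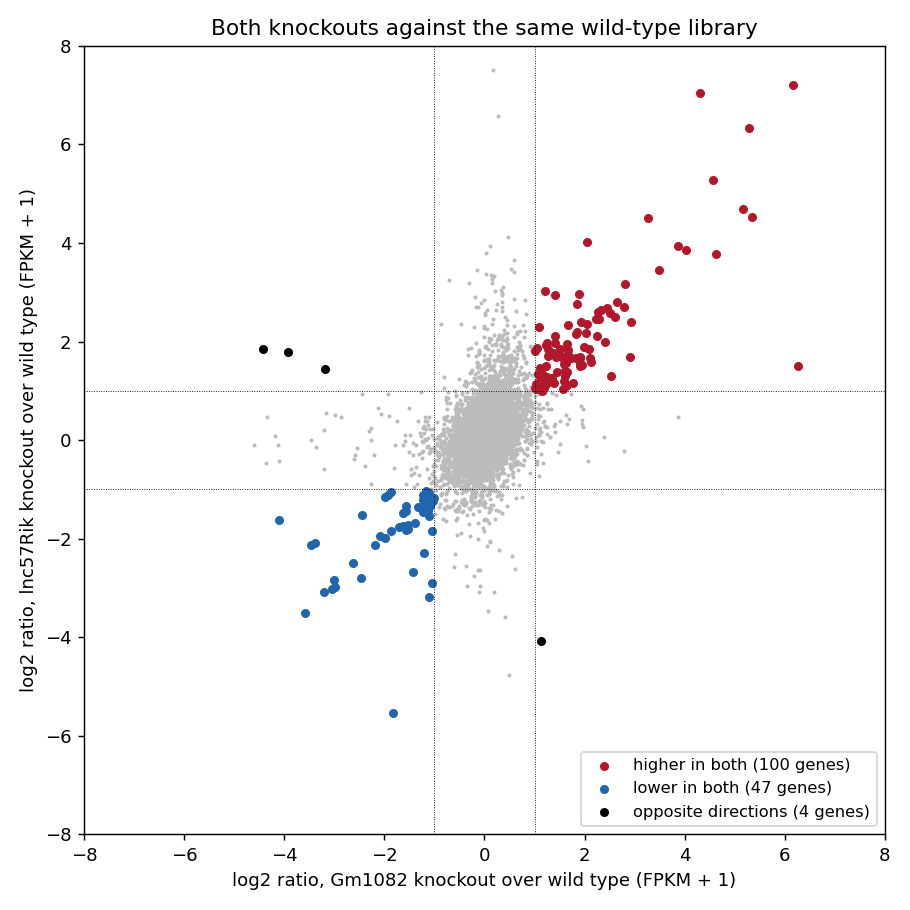
Log2 ratio of each measured mRNA gene in the lnc57Rik knockout (vertical) against that in the Gm1082 knockout (horizontal), both over the same wild-type library. Coloured points passed the size rule in both, with 100 genes higher in both, 47 lower in both and 4 in opposite directions.

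Among lncRNA genes 671 rose and 361 fell in the Gm1082 knockout, 612 rose and 387 fell in the lnc57Rik knockout, and 465 were higher and 491 lower in the lnc57Rik than in the Gm1082 knockout. With median-of-ratios factors the lnc57Rik knockout had 513 up and 446 down, and 420 higher and 561 lower than the Gm1082 knockout, or 114 and 180 at a mean of 5 or more. Assembled transcripts were called more often than NONCODE ones, at 20.1% of 3279 against 5.38% of 6875 in the Gm1082 knockout and at 17.6% against 6.09% in the lnc57Rik knockout. Of 41 measured lncRNA with a symbol 3 rose and 1 fell in the Gm1082 knockout, the snoRNA host gene Snhg20, from 2.77 to 0.363 FPKM. In the lnc57Rik knockout 2 rose and 1 fell, and AW112010, an interferon-inducible transcript, rose from 18.4 to 49.9 FPKM.

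The most extreme lncRNA were mostly listed at 0 in a library and overlapped abundant genes. MERGE.14926.2 (chromosome 17, 39843013 to 39848788) was listed at 0, 3919 and 0 FPKM in wild type, the Gm1082 knockout and the lnc57Rik knockout and overlaps the ribosomal RNA gene Rn18s-rs5, and MERGE.14925.9, on the other strand there, was listed at 0, 332 and 0. Summed over the 20 transcripts at that gene, the abundance was 5049, 7343 and 4202 FPKM, so at least part of this difference lies in which transcript the reads were counted for. MERGE.6652.1, listed at 0, 317 and 0, overlaps Actg1, and MERGE.16904.3, listed at 0, 274 and 0, overlaps Prdx5. MERGE.23568.2, which overlaps Txn1, was listed at 121, 0 and 0 FPKM. NONMMUT021642.2 overlaps Lcp1, with 0.118, 193 and 279 FPKM, and NONMMUT042943.2 overlaps Slc7a11, with 0.111, 0.127 and 146 FPKM. MERGE.19031.8 (chromosome 2, 75638377 to 75642869) overlaps 0 genes of the mRNA table and was listed at 198, 175 and 0 FPKM, and MERGE.5691.1, across Ccl3 and Ccl6, at 93.1, 96.2 and 0 FPKM. MERGE.27283.2, opposite Actb, stood at 233, 3.54 and 1.60 FPKM. In the same order, the others were listed at 67.5, 0 and 26.6 FPKM for MERGE.5779.9, 0, 230 and 155 for MERGE.5779.7, 57.5, 0 and 238 for MERGE.14925.11, also at the ribosomal RNA gene, and 57.0, 0 and 0 for MERGE.2998.4, which overlaps Ddit4. Those that overlap a gene are uncertain, since reads of that gene can be counted for them.

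At a log2 ratio of 1 and a p-value of 0.05, the authors' deposited table calls 1928 mRNA transcripts higher and 2127 lower of 30587 in the Gm1082 knockout. For the lnc57Rik knockout the authors' deposited table calls 2620 higher and 2273 lower of 31250. These are counts of transcripts under another filter, with log2 ratios close to those of the abundances without a pseudocount. The comparisons of summed genes above called a smaller share, but the shares are not measured alike.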

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

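Among the tests below, the share of calls kept among genes with an overlapping value, the comparison between the knockouts, the neutrophil median and the other selections of the second B-lineage list were chosen only after the result was seen.

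4 genes passed the size rule in opposite directions in the 2 knockouts, and for each the difference was not tested. Acod1 stood at 148 FPKM in wild type, 8.79 in the Gm1082 knockout and 511 in the lnc57Rik knockout. Hist1h1d was listed at 8.14, 0 and 23.7 FPKM. Hist1h2ae stood at 25.8, 0.248 and 95.9 FPKM. Ptges stood at 23.2, 51.9 and 0.427 FPKM, or at 34.2, 54.8 and 11.7 with overlapping transcripts added, where the Gm1082 knockout no longer passed the size rule.

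The mRNA genes called in each knockout may partly be reads counted for overlapping same-strand transcripts of the lncRNA table. Transcripts on the other strand were not added, so their part was not tested. In the Gm1082 knockout 109 called genes lost the call with those transcripts added, against 79 to 102 in 100 random exchanges of the added values, so this explanation stays possible for part of the calls. Of the 189 called genes with an overlapping value 42.3% kept the call, which cannot tell how far this explanation reaches. The other 116 had no same-strand value to add, so same-strand transcripts cannot be the whole cause. In the lnc57Rik knockout 126 lost the call, against 135 to 172 in random exchanges, and 65.2% of the 362 with an overlapping value kept it. Another 344 called genes had no overlapping value on the same strand, so there too same-strand transcripts are excluded as the whole cause. This explanation stays open for single genes such as Cyba (-3.47, or 0.56 with those transcripts added). A genotype effect and a difference between cultures both stay open for the rest.

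The guanylate-binding protein and GTPase genes, higher in the lnc57Rik knockout, could reflect the scale of that library, an unusual wild-type library, RNA of B cells or an interferon response. The lowest median over 3 rescalings was 1.49, which excludes scale, and the median between the knockouts was 1.31, which excludes the wild-type library alone. The summed rise of these genes was 1.69 times that of the B cell markers, 240.4 against 142 FPKM, which cannot tell whether B cells carry it, as no B cell profile was used here. An interferon response to the loss of lnc57Rik, or to something else in that culture, stays open.

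B cell markers, higher in the lnc57Rik knockout, could be RNA of B-lineage cells in that culture, a smaller share of macrophages, or B cell genes switched on in macrophages. A second list of 29 B-lineage genes, 3 of them also in a fixed list, had a median of 1.83 over 23 measured genes. Of these 17 were higher and 0 lower, though the rise itself brought some genes past the minimum. Of its immunoglobulin genes, Ighd, Iglc1 and Iglc2 rose. The more abundant Igkc went from 56.4 to 100 FPKM and Ighm from 5.57 to 10.9 FPKM, below the size rule. Over all 29 with no minimum the median was 1.72, with 19 higher and 0 lower, and over the 11 at 1 FPKM or more in wild type it was 0.86, with 5 higher, so B-lineage cells stay possible. A smaller macrophage share alone would raise all other cell types alike. The neutrophil markers had a median of -0.16 and the stromal cell markers one of -0.37, so an equal rise of all was not seen. Dendritic cell markers (0.91) and mast cell, basophil and eosinophil markers (0.82) were higher, however. A smaller macrophage share as part of the cause is therefore not excluded. The macrophage identity list itself had a median of -0.10 at percentile 5.72, or -0.19 at percentile 1.18 with a mean of 5 or more. Some smaller share thus stays possible, and genes switched on in macrophages were not tested.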

How the results depend on the processing

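The alternatives with overlapping transcripts added and with assembled transcripts left out were chosen after seeing the data, as were their tests. No paired analysis was possible because each genotype has 1 library and the labels name no pairs. An interval for counting error was not run, as the tables give no counts. Counts of called genes follow in the order Gm1082 knockout against wild type, lnc57Rik knockout against wild type and lnc57Rik against Gm1082 knockout. From 305, 706 and 603 mRNA genes and 1032, 999 and 956 lncRNA genes, a pseudocount of 0.1 gave 505 (first) and 928 (last) mRNA genes and 1838, 1654 and 1603 lncRNA genes, and a pseudocount of 5 gave 141, 306 and 234 and 342, 361 and 354. A mean of 5 or more gave 429 and 355 mRNA genes in the last 2 comparisons and 332, 301 and 294 lncRNA genes. The most abundant transcript gave 722, 1067 and 1010 mRNA genes. A 1.5-fold rule gave 881, 1887 and 1812 mRNA and 2368, 2257 and 2172 lncRNA genes, and a 4-fold rule 79, 145 and 109 mRNA and 379, 406 and 413 lncRNA genes. Without assembled transcripts the lncRNA counts were 374, 422 and 405. The overlap of the knockouts, 147 genes, was 237 and 69 with pseudocounts of 0.1 and 5, 329 with the most abundant transcript, and 409 and 36 with the 1.5-fold and 4-fold rules. In the lnc57Rik knockout 26 lists stood apart, and 17 with the most abundant transcript. Signs reversed for the erythroid and megakaryocyte list between the knockouts, at -0.0057 with no filter and -0.39 at a mean of 5 or more, and for Traf3 in the lnc57Rik knockout with the most abundant transcript (-0.31). With overlapping transcripts added they reversed for Ifi203 (-0.10), Hspa1b (2.41) and Hspa1a (1.53) in the Gm1082 knockout and for Cyba (0.56) and Ripk2 (0.45) in the lnc57Rik knockout, and the cause was not tested. Of 1678 log2 ratios of named genes under the alternatives 1584 kept their side of the size rule. Their size could differ, as for Bcl2a1d in the lnc57Rik knockout (-2.27 from -5.54 with overlapping transcripts added). Ratios below the size rule in both settings counted as kept even where their sign changed. The 190 with no minimum on the mean and the 162 at a mean of 5 or more could not change, as a filter leaves the ratio as it is. Of 1080 list medians 996 kept their side of the percentile bounds. The overlap was 118 with overlapping transcripts added, 70 higher and 48 lower in both.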

Other observations

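The tests on KEGG pathways below were added after the data files were opened, and the abundant genes were chosen after their values were seen, with no tests run on them. All 3 libraries held much RNA of neutrophil and inflammatory genes beside macrophage genes, although the labels name M-CSF cultures and no stimulus. The neutrophil alarmin S100a9 stood at 4000.2, 2616 and 3998 FPKM and Ngp, a granule gene of immature neutrophils, at 1081, 972 and 1010.4 FPKM, in wild type, the Gm1082 knockout and the lnc57Rik knockout. The chemokine genes Cxcl2 and Ccl3 stood at 1396, 1747 and 955 FPKM and at 1369.6, 1714 and 1136 FPKM, and inducible nitric oxide synthase, Nos2, at 777, 953 and 359.8 FPKM. Csf1r stood at 134, 111 and 88.9 FPKM and the mannose receptor gene Mrc1 at 3.55, 3.46 and 2.29 FPKM.

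Of 243 KEGG pathways 27 stood apart above and 30 below in the lnc57Rik knockout, and 20 and 16 in the Gm1082 knockout, against 6.08 on each side by chance. In the lnc57Rik knockout, DNA replication had a median log2 ratio of 0.53 over 34 genes, 5 of them higher, and base excision repair one of 0.51 over 32 genes, 3 of them higher. Retinol metabolism had a median of -0.42 over 15 genes, 2 of them lower. In the Gm1082 knockout the ribosome pathway had a median of -0.20 over 126 genes, 1 higher and 3 lower, and cytokine-cytokine receptor interaction one of 0.13 over 124 genes, 7 higher and 1 lower.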
